A study of Mus musculus with 2 samples.

How the data were processed

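The series held 2 libraries of total RNA from G1E-ER4, a mouse erythroid line that lacks its own Gata1 and carries a form of the factor that works only when estradiol is bound. Both cultures had received 10 nM 17beta-estradiol for 24 h, and the labels number them as biological replicates 1 and 2. Libraries were made with the ScriptSeq kit from 100 ng of RNA after ribosomal RNA had been removed, over a size range of 200 to 1000, per the labels. No untreated library was analysed here, so levels and ratios within libraries and differences between the replicates were measured, and no change caused by estradiol was tested.

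The authors deposited 1 gene table and 1 transcript table for each library. The gene and transcript counts in the deposited tables are expected counts, per the file headers, and they are not all whole numbers. TPM was deposited beside an effective length and a posterior mean TPM, per the file headers; it is a length-scaled share of the library with the same sum in each library. FPKM values were deposited in the same tables and entered only as an alternative. The percent of a gene's TPM held by each transcript was deposited in the transcript tables, per the file headers. The tables also held credible bounds of TPM and the posterior SD of the count; the level of the interval was not given in the sources used here. The assembly was mm10 and the annotation GENCODE M4, per the text lists deposited with the tables. The program and the aligner, their versions and whether strand was used in the counting were not given in the sources used here.

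Symbols, gene types and coordinates came from GENCODE M21, which is on the same assembly (GRCm38), joined on gene identifiers without their version. Of 43346 Ensembl rows, 42462 matched and 884 did not; the rows without a match held at most 0.145% of the counts of a library. A further 26248 rows carry numeric identifiers and name no gene; they held 18 and 5 counts, at most 2.9e-05% of a library, and stayed out of library sizes and comparisons. The 97 spike-in and phage rows held 0 counts. Hbb-b1, Hbb-b2, Ahsp and Snhg1 had no match and were not analysed here. Values of a few other genes that the rule for named genes takes are not reported here.

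Total expected counts were 62081014 in replicate 1 and 41051163 in replicate 2. A count of 3 is used as the floor for a gene with no reads. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Because small structural RNAs take most of the TPM, protein-coding genes of the nucleus hold only a part of it. Multiplying by 7.09 in replicate 1 and 6.95 in replicate 2 puts a deposited TPM on a scale on which these genes alone make up the full sum.

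Before the data were examined, 28 gene lists, 24 gene pairs, 20 genes for isoform shares, the alternatives and the rule for the genes named in the text were fixed. The rule takes Gata1, every gene of the pairs, up to 4 members of each list with the highest mean TPM and up to 2 under 1 TPM, the 10 nuclear protein-coding genes with the highest mean TPM, the isoform genes and the 10 genes with the largest replicate ratio in each direction. Epb42, Ctsg, Elane, Lyz2, Ngp, Mcm6, Rrm2, Kdm5d and Uty fall outside this rule and were chosen after their values were seen, as were the retained-intron shares of Slc25a37 and Sf3b1 as a result of their own. The place of each list was given as the percentile of its median log2(TPM + 1) among 10000 random lists of the same size drawn from protein-coding genes with a mean of at least 0.1 TPM. A pair was called where the log2 ratio of TPM had the same sign in both replicates and a mean larger than its SD; deposited TPM has few decimals, so values under 0.1 TPM were recomputed for the ratios from the count and the effective length. That step was added after values had been seen, and with the deposited TPM as rounded the number of called pairs was also 21. With 2 replicates the smallest p of an exact two-sided sign-flip test is 0.5, so that test cannot call a pair, and no p is printed for pairs.

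Replicate differences of lists were medians of the log2 TPM ratio, replicate 2 to replicate 1, over members with a mean of at least 1 TPM, centred on the median of expressed protein-coding genes. They were placed among 10000 random lists matched on expression in 20 bins. Replicate differences of genes were counted where the mean expected count was at least 100 and CPM, scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3 with a prior count of 0.5, differed 2-fold or more. The common biological coefficient of variation came from edgeR on expected counts rounded to whole numbers, with an intercept only, over the 11657 genes that filterByExpr kept. DESeq2 1.42.0 gave size factors for an alternative. Other steps used Python 3.11 with pandas, numpy and scipy. On simulated libraries with the real means, library sizes and a coefficient of variation of 10%, the estimate over 12012 genes was 9.98% with no changed gene and 13.5% over 11965 genes when 200 genes had been changed, so real differences between the replicates raise it. With those genes changed 2.5-fold among 9780 tested, the 2-fold rule called 188 of them and 0 unchanged genes. The simulated spread of 10% was below the 17.2% estimated from the real libraries. The 0 unchanged genes called therefore need not carry over to them. Of 200 simulated lists of 24 genes drawn from 7966, the list procedure put 10 outside the middle 95% with no shift. Those lists came from the same genes as the random lists, so a share of that order was set by the design. With a log2 shift of 0.5, all 200 lay above the middle 95%. Smaller shifts and shorter lists were not simulated.

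Each result was computed again under other settings. These were other pseudocounts, thresholds and filters, posterior mean TPM, FPKM or expected counts in place of TPM, DESeq2 size factors or library totals, and each replicate left out. Chosen after seeing the data were TPM rescaled over protein-coding genes for the number of expressed genes, random lists matched on length too, removal of the read density of olfactory receptor genes, pair ratios from deposited TPM as rounded, and the restriction to protein-coding genes with a small posterior SD. The count of 5 used for silent genes, and the rules by which a correlation or a coefficient of variation was said to have moved, were also set after values had been seen. Nuclear copies of mitochondrial mRNAs were taken as pseudogenes with a blastn match of at least 150 bases at 80% identity, limits set before the sums were seen.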

Results

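RNA from estradiol-induced G1E-ER4 cells was measured in 2 libraries of 1 group, each from its own labelled biological replicate. Library totals were 62081014 expected counts in replicate 1 and 41051163 in replicate 2. Reads fell on 16115 genes in replicate 1 and on 19353 in the shallower replicate 2. To check for a library deposited more than once, counts were compared by chi-square over the 12223 genes with a mean count of at least 10, and the statistic of 75.8 per degree of freedom left both libraries counted as separate samples. Values below are means ± SD (n = 2) in deposited TPM, unless another unit is named.

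Gata1, the erythroid transcription factor that the line was built around, stood at 66.6 ± 9.32 TPM (ENSMUSG00000031162.10). It was measured at 60.1 TPM in replicate 1 and at 73.2 TPM in replicate 2 (GRCm38 chromosome X, 7959260 to 7978071, minus strand), from 20658 and 17432 counts. The gene and transcript rows used here do not separate reads of the introduced form from those of the chromosomal gene, which holds for each Gata1 value below as well. Because the line lacks its own Gata1, no Gata1 level, transcript share or ratio to Gata2 given here can be read as that of a native gene. Other factors of the erythroid programme were measured as well. Lmo2, a bridging partner in GATA1 complexes, was at 76.1 ± 9.41 TPM, Nfe2 at 50.2 ± 2.20 TPM, Zfpm1, the GATA1 cofactor known as FOG1, at 43.4 ± 0.156 TPM, and Klf1, the activator of adult beta globin, at 27.8 ± 0.389 TPM. Of the 23 measured erythroid regulators, 20 reached 1 TPM in both replicates. Sox6 (0.080 ± 0.0141 TPM) and Trim58, with 0 counts in both libraries, were among the 3 that did not. The median of the list lay at percentile 93.1 among random lists, inside their middle 95%.

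Hbb-bs and Hba-a2 were among the 10 nuclear protein-coding genes with the highest mean TPM. Hbb-bs was at 1307 ± 455 TPM (chromosome 7, 103826534 to 103828096), Hba-a2 at 1018 ± 124 TPM (chromosome 11, 32296489 to 32297298), Hba-a1 at 291 ± 41.4 TPM and Hbb-bt at 214 ± 39.0 TPM. The embryonic beta-like genes were under 1 TPM, with Hbb-bh1 at 0.715 ± 0.276 TPM (44 and 51 counts) and Hbb-y at 0.205 ± 0.120 TPM (11 and 18 counts). Hba-x, Hbq1a and Hbb-bh2 had 0 counts. Hba-a1 and Hba-a2, and likewise Hbb-bs and Hbb-bt, are near-identical copies, so the split of reads within each couple is uncertain. Because 5 of the 10 measured globin genes were under 1 TPM in both libraries, the list median lay at percentile 0.28.

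All 15 genes of haem synthesis reached 1 TPM in both replicates, and their median was 39.7 TPM (31.5 and 48.0 TPM in replicates 1 and 2; percentile 100 among random lists). Tmem14c, which carries a haem precursor within the mitochondrion, was at 238 ± 7.55 TPM, Abcb10 at 110 ± 5.84 TPM, Alas2, the erythroid enzyme of the first step, at 82.7 ± 2.12 TPM, and Cpox at 60.1 ± 5.59 TPM. Of the 17 iron genes, 16 reached 1 TPM in both libraries. Ftl1, the ferritin light chain, led at 1578 ± 47.4 TPM, followed by Tfrc, the transferrin receptor, at 187 ± 32.0 TPM, Glrx5 at 171 ± 2.57 TPM and Fth1 at 134 ± 18.8 TPM. The iron list lay at percentile 77. For haem export and breakdown the percentile was 92.9, with 8 of 9 members at 1 TPM in both libraries. There, Blvrb was at 149 ± 2.56 TPM, Hebp1 at 77.2 ± 7.29 TPM and Flvcr2 at 0.010 TPM in each library.

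Red cell membrane genes were high as a group, with 23 of 27 members at 1 TPM in both replicates and a percentile of 99.9. Car2, a carbonic anhydrase, was at 244 ± 10.4 TPM, Add1 at 76.3 ± 4.47 TPM and Sptb, the erythroid beta spectrin, at 68.5 ± 1.53 TPM. Slc4a1, the anion exchanger of the mature red cell, was at 3.52 ± 0.898 TPM, and Epb42 was at 0.645 ± 0.219 TPM. Aqp1 had 0 and 20 counts and Tmod1 stood at 0.160 ± 0.0566 TPM. Genes of cell protection were high as well: the antioxidant list (percentile 99.9; 15 of 15 members at 1 TPM) was led by Prdx2 at 593 ± 28.5 TPM and Gpx1 at 274 ± 15.3 TPM. The list of stress and heat shock genes (percentile 100; 12 of 17 members) was led by Hspa8 at 529 ± 86.4 TPM, Hsp90aa1 at 120 ± 17.4 TPM, Ddit3 at 91.9 ± 8.94 TPM and Asns at 76.9 ± 0.346 TPM, while Hspa1a and Chac1 were under 0.1 TPM.

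**Figure D1:**
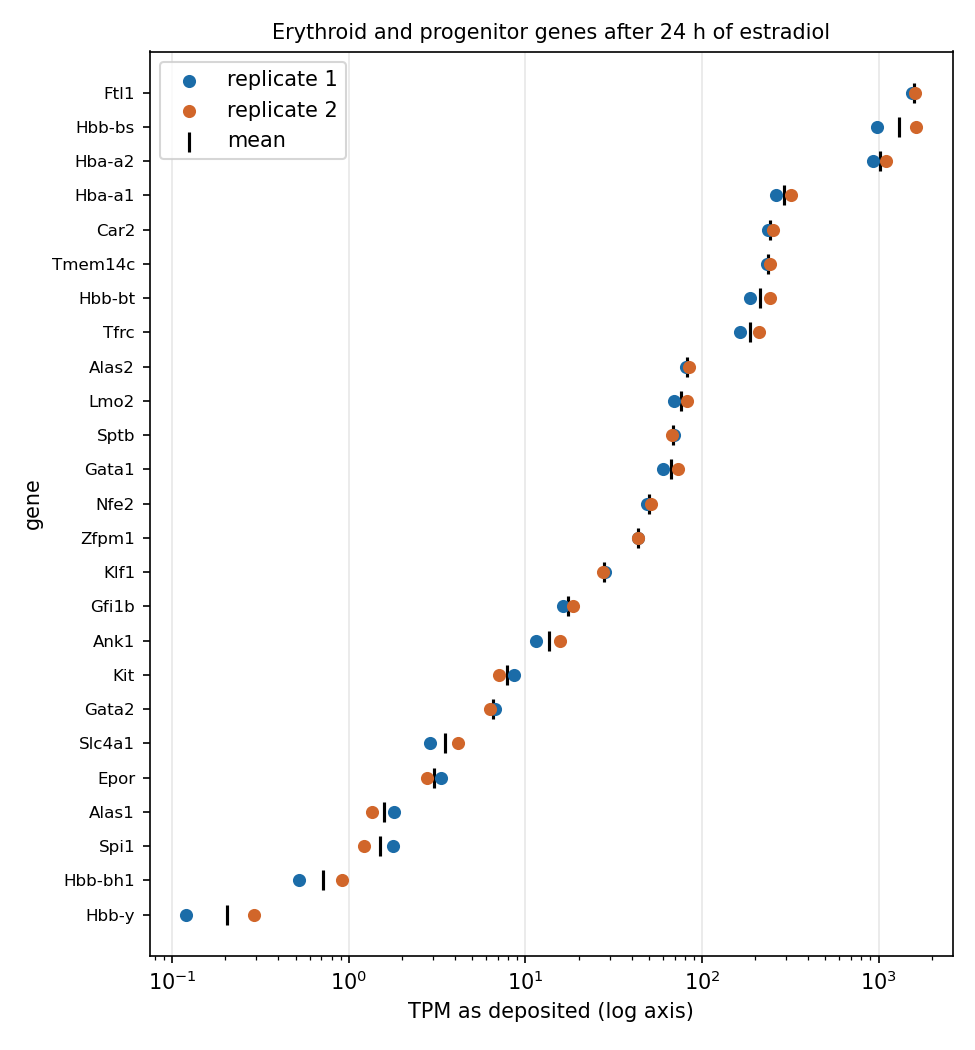
Deposited TPM on a log axis (horizontal) for 25 erythroid and progenitor genes (vertical), with 1 point for each replicate library and a bar at the mean. Ftl1, Hbb-bs and Hba-a2 have the highest means, with Hbb-bs at 985 and 1629 TPM, and Hbb-y lies lowest at 0.12 and 0.29 TPM.

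Regulators of earlier progenitors had a median of 1.55 TPM (1.67 and 1.63 TPM in replicates 1 and 2), and the erythroid regulators one of 7.89 TPM (7.81 and 7.96 TPM). Gata2, which precedes Gata1 in the lineage, was at 6.53 ± 0.346 TPM and Kit, the stem cell factor receptor, at 7.85 ± 1.10 TPM. Bmi1 (15.2 ± 0.481 TPM), Fli1 (11.5 ± 0.417 TPM), Runx1 (9.84 ± 0.0636 TPM) and Ikzf1 (9.80 ± 0.276 TPM) led the list, and Mecom and Hlf had 0 counts in replicate 1 with 7 and 5 in replicate 2. Of 20 members, 13 reached 1 TPM in both libraries, and the list lay at percentile 0.43. The position did not hold with posterior mean TPM (3.02) or FPKM (2.62). It rose to percentile 93.3 when the random lists were drawn with no filter on low values. Cytokine signalling genes (percentile 16.1; 14 of 19 members at 1 TPM) were led by Csf2rb at 82.6 ± 3.20 TPM, Pim1 at 69.9 ± 1.73 TPM, Csf2rb2 at 49.2 ± 10.7 TPM and Jak2 at 13.2 ± 0.481 TPM, with Epor itself at 3.05 ± 0.396 TPM. Socs3 (0.095 ± 0.0354 TPM) and Insr were under 1 TPM. In the survival list (percentile 46.5; 13 of 20 members at 1 TPM) Mcl1 was at 44.1 ± 1.97 TPM, Bax at 28.2 ± 1.62 TPM and Birc5 at 20.9 ± 8.08 TPM, and Fas had 0 counts. For autophagy genes (percentile 90.9; 16 of 18 members) Gabarap was at 240 ± 8.64 TPM, Sqstm1 at 105 ± 6.56 TPM, Map1lc3b at 70.7 ± 6.48 TPM and Bnip3l, a mitophagy receptor, at 58.9 ± 14.8 TPM.

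Markers of other cell types were low. All 15 lymphoid, all 14 stromal or endothelial and all 13 pluripotency markers were under 1 TPM in both libraries, with 6, 8 and 7 of them without reads. Among the 16 myeloid markers only Fcgr3 reached 1 TPM in both (1.21 ± 0.0990 TPM), followed by S100a8 at 0.03 and 0.60 TPM, S100a9 at 0.02 and 0.38 TPM and Mpo at 0.05 and 0.29 TPM. Elane (1 and 9 counts), Ctsg (0 and 8) and Lyz2 (0 and 17) also had more reads in the shallower replicate 2. Hdc, a histidine decarboxylase of mast cells, was at 14.7 ± 2.06 TPM, and the other 12 of the 13 mast cell markers were under 1 TPM, led by Mcpt2 at 0.585 ± 0.0778 TPM. Of 16 megakaryocyte markers, 4 reached 1 TPM in both: Tubb1 (8.21 ± 2.03 TPM), Itgb3 (1.99 ± 0.156 TPM), Itga2b (1.87 ± 0.240 TPM) and Gp1ba (1.64 ± 0.283 TPM). Interferon response genes (6 of 15 members at 1 TPM) included Irf9 at 9.38 ± 1.24 TPM, and immediate early genes (4 of 12) were led by Jund at 6.24 ± 0.679 TPM. Oestrogen response genes reached 1 TPM only for the coactivators and corepressor Ncoa3, Ncoa2, Nrip1 and Ncoa1 (4 of 11), and Greb1 had 3 and 1 counts. The globin, progenitor, immediate early, interferon, oestrogen, sex chromosome and 6 cell-type marker lists lay below the middle 95% of random lists, 12 in all. This count fell to 0 when the random lists were drawn with no filter on low values, because the comparison then includes genes with no expression. The lists kept members under the 0.1 TPM asked of the genes in the random lists. A list with a median under 0.1 TPM was therefore almost bound to come out low.

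Genes of growth and division were abundant. The proliferation list reached percentile 99.9, with 23 of 24 members at 1 TPM in both libraries, and its highest members were Top2a at 66.0 ± 24.3 TPM, Ccnb1 at 50.2 ± 16.3 TPM, Ccna2 at 38.9 ± 14.4 TPM and Ccnd3 at 30.7 ± 2.91 TPM. The list of inhibitors and pocket proteins lay at percentile 69.7 (9 of 12 members at 1 TPM), with Btg2 at 84.5 ± 6.46 TPM, Cdkn2c at 41.1 ± 5.11 TPM, Cdkn1b at 36.2 ± 4.00 TPM and Rb1 at 11.7 ± 0.163 TPM, and Cdkn2a and Cdkn2b had 0 counts. Ribosomal protein genes had a median of 196 TPM (200.0 and 191 TPM in replicates 1 and 2) and histone genes a median of 56.2 TPM (31.1 and 76.1 TPM), both at percentile 100. Rpl7 was at 752 ± 31.7 TPM, Rplp1 at 744 ± 66.0 TPM, Rpsa at 687 ± 91.9 TPM, Hist1h4k at 668 ± 474 TPM and Hist1h4d at 455 ± 237 TPM. Both families have many near-identical copies, so single members are uncertain. Other abundant genes were Eef1a1 at 1394 ± 15.0 TPM and Mt1, a metallothionein, at 991 ± 194 TPM.

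Related genes were compared as ratios within each library, and 21 of 24 pairs were called. How often pairs of unrelated genes would pass the same rule was not measured, so the number only describes these pairs. It includes the pairs with few reads named below. Adult beta globin exceeded embryonic beta-like globin by 1690-fold (log2 ratio 10.72 ± 0.16, n = 2), and alpha globin was at least 35547-fold above Hba-x, taken at a floor of 3 counts per library. Gata1 exceeded Gata2 by 10.2-fold (log2 3.35 ± 0.28), Klf1 exceeded Spi1, a myeloid factor, by 18.9-fold (log2 4.24 ± 0.37), and Alas2 exceeded Alas1, the housekeeping form, by 52.9-fold (log2 5.73 ± 0.34). Sptb lay 15.8-fold above Sptbn1, Bcl2l1 52.1-fold above Bcl2, Tfrc 149-fold above Tfr2, Car2 32.6-fold above Car1, Hk1 26.9-fold above Hk2 and Cdkn1b 14.0-fold above Cdkn1a. Smaller ratios were 3.69-fold for Hbb-bh1 over Hbb-y, which rested on 11 and 18 counts of Hbb-y, 2.65-fold for Slc25a37 over Slc25a28 and 2.33-fold for Nfe2 over Nfe2l2. Pkm exceeded Pklr by 10.2-fold, Slc2a3 exceeded Slc2a1 by 8.99-fold and Kit exceeded Epor by 2.57-fold. Gfi1 (14 and 5 counts), Zfpm2 (5 and 2), Ccnd1 (6 and 5) and Ank3 (0 and 8) had too few reads for a useful ratio and lay far below Gfi1b, Zfpm1, Ccnd3 and Ank1 in both libraries. Among the pairs not called, alpha against adult beta globin (log2 -0.18 ± 0.29) and E2f2 against E2f1 (0.13 ± 0.80) did not exceed their spread; on expected counts not divided by length both were called (-0.69 and 0.97). The size of many called ratios moved by over 1.5 times with the setting, without a change of sign. On expected counts not divided by length, the log2 ratio went from 1.41 to 3.22 for Slc25a37 over Slc25a28, from -1.36 to -2.90 for Epor over Kit, from 1.22 to 0.38 for Nfe2 over Nfe2l2, from 3.35 to 2.52 for Gata1 over Gata2, from 5.70 to 4.01 for Bcl2l1 over Bcl2, from -3.35 to -4.35 for Pklr over Pkm, from -3.17 to -3.86 for Slc2a1 over Slc2a3, from 5.03 to 5.84 for Car2 over Car1 and from 3.81 to 4.73 for Cdkn1b over Cdkn1a. With a pseudocount of 1 it went from 1.88 to 0.50 for Hbb-bh1 over Hbb-y, from 10.72 to 9.61 for adult over embryonic beta globin, from 15.12 to 10.35 for alpha globin over Hba-x, from 4.24 to 3.54 for Klf1 over Spi1, from 5.73 to 5.03 for Alas2 over Alas1, from 5.70 to 3.73 for Bcl2l1 over Bcl2 and from 7.22 to 6.38 for Tfrc over Tfr2. With 2 replicates the exact two-sided sign-flip test of a pair cannot give a p under 0.5.

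**Figure D2:**
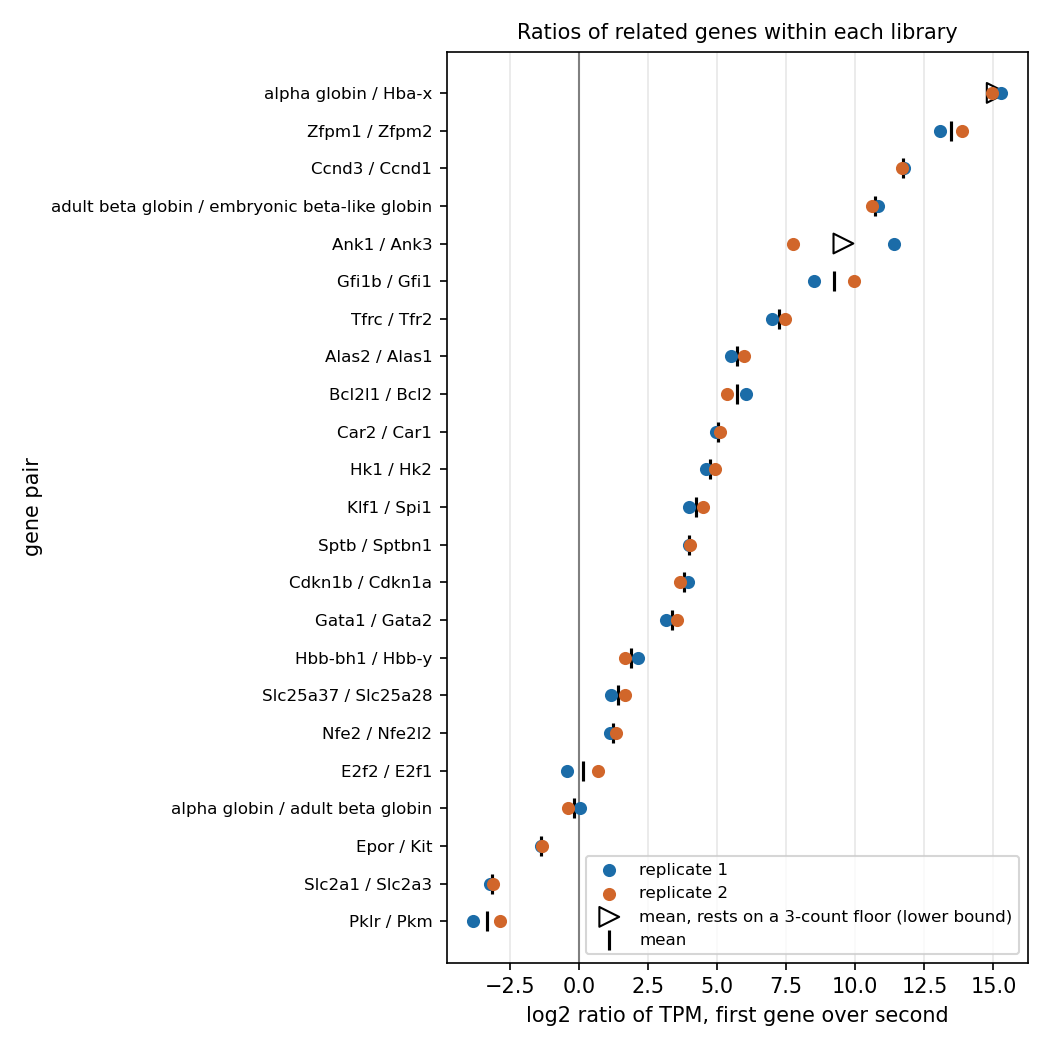
Log2 ratio of TPM, first gene over second (horizontal), for 23 of the fixed pairs (vertical), with 1 point for each replicate, a bar at the mean and an open arrow where the mean rests on a floor of 3 counts. Alpha over adult beta globin and E2f2 over E2f1, which were not called, have the means -0.18 and 0.13.

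Transcript shares varied between genes. Gata1-201 held 98.9 ± 0.629% of Gata1 TPM, Tal1-201 91.5 ± 5.35% of Tal1 and Lmo2-208 85.9 ± 0.827% of Lmo2. Alas2-201 held 75.1 ± 0.424% of Alas2, Alad-201 85.2 ± 1.51% of Alad and Slc4a1-201 97.2 ± 4.02% of Slc4a1, while Fech and Epor each have 1 transcript in the tables. Ank1 was spread over several forms, the largest of them at 26.4 ± 1.05%, and Uros-208 held 30.9 ± 2.58% of Uros. Kit was divided between Kit-201 at 54.1 ± 0.955% and Kit-204 at 38.5 ± 0.0566%. Transcripts annotated as retained introns held 45.0 ± 5.50% of Slc25a37, the mitochondrial iron importer (48.9% and 41.1%), and 36.4 ± 4.40% of Sf3b1, a splicing factor, against a median of 11.6% over the 3485 expressed protein-coding genes that have such a transcript. Among these genes Slc25a37 lay at percentile 90.8 and Sf3b1 at percentile 86.1. In Tfrc the share was 18.2 ± 2.82%, in Runx1 15.6 ± 1.91%, in Uros 11.3 ± 2.61%, in Alas2 7.43 ± 0.934%, in Kit 7.40 ± 0.866%, in Ank1 7.01 ± 0.323% and in Bnip3l 1.06 ± 0.479%. Pklr-205, at 60.2 ± 8.93% of Pklr TPM, rested on only 66.9 and 91.5 expected counts. Shares are of TPM, so a short transcript can hold a large share on few counts. Uros-208 rested on 384 and 228 counts, against 755 and 776 for Uros-201, which held 15.8%. Bnip3l-206 held 26.2 ± 4.58% on 1019 and 359 counts, against 18574 and 12127 for Bnip3l-201. The retained-intron form Sf3b1-205 held 10.4 ± 2.54% on 1029 and 463 counts, against 63922 and 42081 for Sf3b1-201. Shares of counts were not computed. Epb41-215 held 49.6 ± 4.44% of Epb41, Bcl2l1-209 31.7 ± 5.40% of Bcl2l1, Runx1-201 39.6 ± 4.20% of Runx1, Bnip3l-201 50.7 ± 10.8% of Bnip3l, Tfrc-201 78.7 ± 3.14% of Tfrc, Slc25a37-201 46.2 ± 5.04% of Slc25a37 and Sf3b1-201 53.7 ± 0.170% of Sf3b1.

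Small structural RNAs took most of the TPM. Small nuclear RNA genes held 44.8 ± 0.885% and the 7SK and 7SL class 30.6 ± 0.258%, while protein-coding nuclear genes held 14.2 ± 0.207%. The 7SK and 7SL class was taken as all 562 genes annotated as misc_RNA, so it is not limited to these 2 RNAs. By expected counts, protein-coding nuclear genes held 79.1 ± 1.44% and small nuclear RNA genes 1.76 ± 0.487%. The noncoding list (percentile 99.95) included Rn7sk at 110348 ± 20233 TPM, Rmrp at 8747 ± 239 TPM, Malat1 at 1982 ± 330 TPM and Rpph1 at 1638 ± 52.0 TPM, and Airn had 0 counts. Nuclear rRNA genes had 0 counts in both libraries, which by counting error alone allows up to 7.31e-06% of the counts. The program and the aligner are not given, so how reads of rRNA were treated is unknown. The value is therefore no bound on the rRNA content of the libraries. The mitochondrial ribosomal RNA genes held 0.0311 ± 0.00648% of TPM. Mitochondrial mRNAs (percentile 100, all 13 at 1 TPM) held 0.442 ± 0.0297%, with mt-Co1 at 2655 ± 338 TPM, mt-Atp8 at 722 ± 113 TPM, mt-Nd1 at 272 ± 10.7 TPM and mt-Co3 at 247 ± 39.9 TPM. Nuclear copies share reads with several of these genes, so their levels are uncertain. Globin genes held 0.283 ± 0.0661% of TPM, and 1.98 ± 0.435% once TPM was restricted to protein-coding nuclear genes; the 10 most abundant nuclear protein-coding genes held 6.85 ± 0.687% on that scale. The libraries contained 8500 genes at or above 1 TPM in both replicates, of which 7794 were protein coding. The number ranged from 4743 at 5 TPM to 10740 (9214 protein coding) with TPM rescaled over nuclear protein-coding genes, a setting chosen after seeing the data.

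Levels in the replicates were correlated across genes. Pearson r of log2(TPM + 1) was 0.991 and Spearman rho 0.870 across the 43346 Ensembl genes; genes are not independent replicates. The common biological coefficient of variation was 17.2%. Of 9777 genes with a mean count of at least 100, 205 differed 2-fold or more, 159 higher in replicate 2 and 46 higher in replicate 1. The largest ratios belonged mostly to pseudogenes, small RNA genes and unnamed gene models, which can share reads with copies and are uncertain. Gm12671, Rnu3b2, Rnu3b4, Rnu1b1, Gm6311, Gm14434, Gm14440, Nanp, Rpl30-ps9 and mt-Atp6 were highest in replicate 1, and Gm7336, Gm26870, Gm10801, Gm10719, Gm2810, Gm28967, Gm10800, Gm21738, E2f7 and Gm10717 in replicate 2. Among protein-coding genes whose posterior SD was under 5% of the count, a restriction chosen after seeing the data, 135 were higher in replicate 2 and 13 in replicate 1.

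Gene groups also differed between the libraries. Histone genes were 2.32-fold higher in replicate 2 at the median (log2 1.21; 56 of 57 members higher), and proliferation genes 1.83-fold (log2 0.87; 22 of 23 members). Mcm6 was at 5.92 and 16.3 TPM, Rrm2, a subunit of ribonucleotide reductase, at 11.2 and 28.3 TPM and Top2a at 48.9 and 83.2 TPM. Stress and heat shock genes were 1.17-fold higher in replicate 2 (percentile 99.7), while mitochondrial mRNAs had a median log2 ratio of -0.20 (percentile 0.25) and interferon genes of -0.25 (percentile 1.84). Some mitochondrial mRNAs share reads with nuclear copies unevenly between the libraries. mt-Atp6 had 1499.2 and 186.4 counts, with 42909.8 and 26809.6 on copies. mt-Co2 had 3168.6 and 3534.5, with 65099.4 and 33504.5 on copies. The list ratio was not computed with copies, so its place is uncertain. The globin list had a ratio of log2 0.36, at percentile 96.9 and inside the middle 95%. It rested on 4 members from couples of near-identical copies, all 4 higher in replicate 2. On TMM-scaled CPM its percentile was 97.48, at the edge of the middle 95%, so its place inside does not show that the replicates agree. The erythroid regulators lay inside at percentile 85.9. The haem list (percentile 95.2) and the iron list (90.5) were also inside, but came out above on TMM-scaled CPM (98.5 and 97.6). The membrane list (95.8) and the antioxidant list (97.4) came out above with lists matched on length too, a setting chosen after seeing the data (98.8 and 98.1), and the autophagy list (7.22) came out below for members of at least 5 TPM (2.16). In all, 3 of 22 lists lay above and 2 below the middle 95% of random lists. By chance 1.1 would be outside if members varied independently, as genes of the random lists were drawn. Members of a fixed list can vary together or share reads, so the number outside by chance may be larger. The percentiles measure the drawing of genes and not the spread between replicates. These values compare 2 libraries, not conditions.

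**Figure D3:**
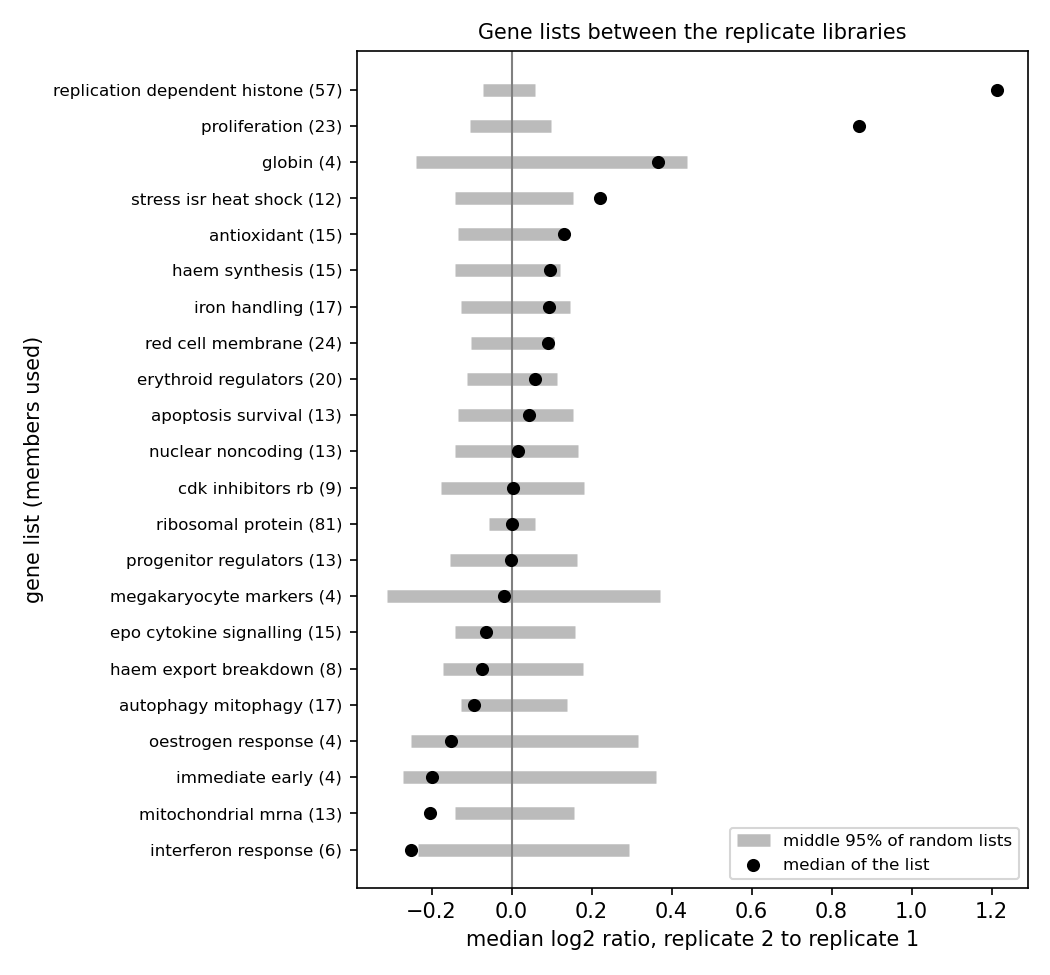
Median log2 ratio, replicate 2 to replicate 1 (horizontal), for 22 gene lists (vertical, with the number of members used), as points beside grey bars for the middle 95% of random lists matched on expression. The histone list (1.21) and the proliferation list (0.87) lie furthest from the bars.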

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

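Reads were found in rows outside the comparisons. The 26248 rows with numeric identifiers, which name no gene here, held 18 expected counts in replicate 1 and 5 in replicate 2. Groups of 2 libraries are too small for an outlier rule, and with 1 group no difference of effects was examined.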

How the results depend on the processing

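The restriction to genes with a small posterior SD, length-matched lists, the removal of olfactory receptor read density, TPM rescaled for expressed genes and pairs from TPM as rounded were chosen after seeing the data. Pairs, levels and shares kept their direction under the alternatives except as given here. Pearson r was 0.989 with a pseudocount of 0.1, 0.985 for genes at or above 1 TPM and 0.995 for protein-coding genes; Spearman rho was 0.977 for genes at or above 1 TPM and 0.936 for protein-coding genes. The coefficient of variation was 22.8% with no filter beyond a count above 0 and 16.2% at a mean count of at least 100. At 5 TPM, 4743 genes and 4377 protein-coding genes remained; leaving out a replicate gave 8728 to 8759 and 7933 to 7950, posterior mean TPM 9706 and 7894, FPKM 10042 and 8860, and rescaled TPM 10740 and 9214. By expected counts, composition moved because length division is absent. It came to 1.76% for small nuclear RNA, 11% for the 7SK and 7SL class, 0.187% for small nucleolar RNA and 79.1% for protein-coding genes. Mitochondrial mRNAs held 1.45%, mitochondrial rRNA 0.140%, globin 0.431% and long intergenic RNA 3.11%. Pseudogenes held 2.29%, the 10 top genes 2.26% and ribosomal proteins 3.57%. Posterior mean TPM gave 0.511% for mitochondrial mRNAs, 0.0401% for nuclear rRNA and 1.57% for pseudogenes. Nuclear rRNA genes had 0 counts in both libraries, so the 0.0401% does not come from reads assigned to them. For mitochondrial mRNAs and pseudogenes the cause was not tested. Restricted to protein-coding nuclear genes, globin held 1.98%, the 10 top genes 6.85%, ribosomal proteins 14.0% and histones 3.76% (2.32% in replicate 1 and 5.20% in replicate 2). With no filter on low values, 16 lists lay above and 0 below the random range. Leaving out a replicate, alpha over adult beta globin ranged from log2 -0.39 to 0.024 and E2f2 over E2f1 from -0.43 to 0.70, with the other sign without replicate 2; neither had been called. Genes differing between replicates numbered 411 (243 and 168) at a mean count of at least 30 and 769 (511 and 258) at 1.5-fold; with protein-coding genes of small posterior SD, 13 were higher in replicate 1. Among lists, pairs and transcripts taken singly, 415 values kept their call or stayed within the spread, 20 gained a call and 14 lost one. With shares from posterior mean TPM, Slc4a1-201 held 88.4%, the main Ank1 form 22.9% and Kit-201 52.9%. Depth limits genes near the floor of 3 counts, such as Zfpm2 and Ank3.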

Other observations

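The tests of sequencing depth, of the granule genes in replicate 1 and without Mpo, and of the mitochondrial mRNAs whose copies hold no reads were chosen only after the results were seen; for the other tests the bounds were written before, although the granule gene counts and the replicate ratios of cell division and histone genes had been seen by then. The labels give a male source, yet Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in replicate 1 and 7, 4, 3 and 2 in replicate 2, and Xist had 23 and 25. Tsix, which overlaps Xist on the opposite strand, had 1152 and 529; the use of strand in the counting is not given in the sources used here, so reads of the pair cannot be assigned with certainty.

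More genes were silent in replicate 1 only, although it was sequenced deeper: 1023 genes had 0 counts there and at least 5 in replicate 2, against 463 the other way, and a ratio of totals, replicate 2 to replicate 1, of 0.661 argues against depth as the source. Olfactory receptor genes, a large family spread over the genome, had 4.41 times as many counts in replicate 2, relative to library totals (interval 3.73 to 5.25, counting error only), so genomic DNA in that library is a candidate source. The 8 granule genes of myeloid cells, led by Mpo (16 and 62 counts), Ngp (0 and 18) and Lyz2 (0 and 17), held 19 and 148 counts, which was 14.4 times the counts per kb of olfactory receptor genes in replicate 1 and 38.4 times in replicate 2 and argues against genomic DNA for these genes. Mpo carried the value of replicate 1: the other 7 genes held 3 counts there, or 2.95 times (interval 0.609 to 8.63, counting error only), against 86 counts or 29.0 times in replicate 2. Reads from other blood cells in library 2 and expression in the line that differed between the cultures cannot be told apart, since no value here separates them, and no biological explanation was tested.

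Cell division and histone genes were higher in replicate 2. Gene length and fragment size are argued against, since the proliferation list stayed at percentile 100 and the histone list at percentile 100 among lists matched on expression and length. Removing the read density of olfactory receptor genes took 0.0163% of the proliferation counts in replicate 2, and the median log2 ratio on the same scale was 0.95 before and 0.94 after, so the removal changed almost nothing. A share of that size argues against genomic DNA as the source. A difference in growth state between the cultures may remain; both carry the same labels, so no biological explanation was tested.

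mt-Co1 stood 10.9-fold above mt-Nd1, the next mitochondrial mRNA in counts per kb (mt-Atp8, mt-Atp6 and mt-Nd4l left out). Adding the counts of nuclear pseudogenes that match each mRNA over at least 150 bases at 80% identity brought mt-Co1 to 1.65-fold above the next, mt-Co3. Reads shared with such copies may therefore account for much of the gap to mt-Co3 (12.6-fold without copies), and for part of that to mt-Nd3 (39.0-fold without and 3.19-fold with copies) and mt-Co2 (82.7-fold and 5.27-fold). For 5 mRNAs (mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5 and mt-Cytb) no copy was found or the copies held no reads. Adding copies could not change their gaps, and mt-Co1 stood 10.9-fold above mt-Nd1, the highest of them. The copies found thus hold no reads that could account for these gaps. Copies not annotated as pseudogenes were not searched, so shared reads are not excluded. mt-Nd6, whose copy held 0 and 4 counts, went only from 285-fold to 284-fold below mt-Co1. These gaps are open, and no biological explanation was tested.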
